A study of Mus musculus with 16 samples.

How the data were processed

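The samples were mouse CD8+ T cells from Pmel mice, whose T cells carry a receptor for a melanocyte antigen, crossed to an LC3-GFP-RFP reporter. LC3 is the protein that coats autophagosomes, and the sort into LC3-GFP positive and LC3-GFP negative cells separated cells by reporter fluorescence. Per the labels' protocols, purified T cells were stimulated for 3 days with antibodies to CD3 and CD28 at 2 µg/ml each in 100 IU/ml IL2, treated with carbon monoxide (CO) for 24 h and sorted. RNA was measured in 2 positive and 2 negative libraries and chromatin accessibility (ATAC-seq, in which the Tn5 transposase cuts open chromatin) in another 2 and 2 libraries of sorted cells, called in vitro here. For the in vivo libraries, sorted cells were transferred into C57BL/6 mice that had carried B16-F10 melanoma for 12 days, and Vβ13+CD8+ cells were sorted from the tumour of each mouse 15 days later, with 4 mice in each group. Samples were grouped by the cell population named in the labels.

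Every library came from CO-treated cells, so the comparisons set LC3-GFP positive against negative cells, and an untreated group was not analysed here. The labels do not say whether the RNA and in vitro ATAC replicates came from separate animals or cultures. Their p-values therefore measure only the spread between these samples, which may be technical.

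The RNA table deposited by the authors holds estimated counts per gene that were not scaled. Between 22.5% and 23.8% of the values in a library were not whole, and no gene had a total under 10 over the 4 libraries. Per the submitters' processing notes, Partek, STAR and DESeq2 were used with the mm10 build. Versions, the counting method, the library kit and its strandedness were not given in the sources used here. RNA was extracted with a mirVana kit, per the labels' protocols. Counts of near-identical copies, overlapping genes and antisense genes are uncertain, because the handling of shared reads and of strand is not given.

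The ATAC tables deposited by the authors list peaks with their position, length in base pairs and caller values, and per the submitters' processing notes they were made with Partek, cutadapt, BWA and MACS2 on mm10. Whether reads were shifted for the Tn5 cut was not given in the sources used here. Each peak carries the name of 1 library, so peaks were called in each library on its own. Per the file headers, the deposited values per peak are the pileup signal at the summit, the fold enrichment over the local background of the same library, and -log10 of the p-value and of the q-value. The smallest -log10 q in the deposited lists was 1.302 in both experiments. These are the authors' values and were used only to rank or filter peaks within 1 library's list. Read depth per ATAC library is unknown from these lists, so the number of peaks stands in for depth.

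For RNA, estimated counts were rounded to whole numbers and genes kept by edgeR's filterByExpr with the group. Library sizes were scaled by TMM, and edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) was run with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are in CPM, edgeR's unit of counts scaled by library size, on TMM-scaled library sizes. Totals ran from 14567540 to 17557628 counts, and 3 counts in a library, the floor used here, were 0.171 to 0.206 CPM. Intervals on ratios of genes with few counts are exact 95% intervals given the summed counts, and they cover counting error only, since reads without molecular identifiers are not independent molecules. The 32 gene lists were fixed before the data were examined. Those with at least 5 tested members (27 lists) were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. None of the 13 mitochondrially encoded transcripts was listed in the table.

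For ATAC, peaks of the libraries of 1 experiment were merged where they overlapped by at least 1 bp. A merged region found in all libraries of 1 group and in none of the other was called positive-only or negative-only. Its number was set beside that of every other split of the libraries, 3 splits in vitro and 35 in vivo with the real one. Similarity was the Jaccard index of covered bases, with an exact one-sided permutation test of the mean within groups minus the mean between groups. Numbers of peaks were compared by two-sided exact permutation tests. Regions were assigned to genes by overlap with gene bodies extended by 2 kb upstream, from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. Strand was known for 12529 of 21906 genes and the others were extended on both sides. Exons, introns and untranslated regions were not used here. Of 658 distinct genes on the lists, 645 could be placed. Each list was tested by a one-sided Fisher's exact test against all other genes with a region, adjusted over lists and directions. The difference in median RNA log2 fold change between genes with positive-only and with negative-only regions had a two-sided permutation test with 100000 resamples over genes, which are not independent replicates.

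The genes named in the text follow a rule. It takes 7 genes fixed in advance, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups (predicted genes left out), and up to 4 called members per list with the largest change, or 2 with the smallest p where none was called. In ATAC it takes up to 10 regions per experiment and direction in genes of the lists and up to 10 over all genes, ranked by the caller's score within each library. Genes outside the rule were chosen after their values were seen. In the account of the lists these are Atf3, Lta, Il2ra, Myc, Irf4, Lag3, Ezh2, Gbp2, Jchain and H2-Ab1. Further genes are given as members of a list that hold a region of one kind.

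The alternatives tried for RNA were DESeq2, its size factors in edgeR, library size alone, other filters on low counts, glmTreat against a 1.2-fold change, limma-voom, the replicate number as a block and leaving out each library. For lists they were an estimated correlation and fry. With an estimated correlation camera also takes its degrees of freedom from the 4 libraries and not from the genes. Passing is then hard at any correlation, so failing there does not show that correlation among members explains a list. For ATAC they were -log10 q of at least 5, the same number of top peaks per library (49634 in vitro, 27406 in vivo), a reciprocal overlap of 50%, promoter regions within 1 kb and leaving out each library. Alternatives chosen after seeing the data were the tests without Rn45s, random gene lists matched on number of regions (10000 draws), and the ATAC lists and the comparison of experiments without 1 in vivo library.

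On simulated counts for the RNA comparison (12022 genes, 200 changed), 54% of changed genes were recovered at 1.25-fold, 60% at 1.5-fold, 94% at 2-fold and 96% at 4-fold, and 4.4% of calls were false. The simulation used the spread fitted to these libraries, which may be technical, and far fewer changed genes than the 3000 called in the data. Its rates hold for that setting alone. In 2000 simulated in vitro regions, all 180 planted positive-only and 120 planted negative-only regions were found. Each was planted in every library of its group and in none of the other. This checks the counting code alone and not how reliable such calls are in real peak lists. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.13 between the positive and 4.38 between the negative RNA libraries. Separate libraries of 1 pool can exceed that noise too, so this does not show separate animals or cultures. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.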

Results

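RNA was sequenced from 4 libraries of CO-treated mouse CD8+ T cells, 2 sorted as LC3-GFP positive and 2 as negative. Total counts were 17557628 and 15605902 in positive replicates 1 and 2 and 15850657 and 14567540 in negative replicates 1 and 2. Of 13275 genes listed, 12022 were tested. ATAC-seq covered 2 positive and 2 negative libraries of the same kind of sorted cells in vitro, with 63761 and 53869 peaks in the positive and 56476 and 49634 in the negative libraries. A further 4 positive and 4 negative libraries came from T cells recovered from melanomas of mice that had received either population, with 27406 to 37477 peaks in the positive and 33704 to 55171 in the negative libraries. The series title concerns autophagy regulated by the kinase PERK after carbon monoxide, and the comparisons ask how cells with and without the LC3-GFP signal differ in transcripts and in open chromatin. Coordinates are on mm10.

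In the sorted cells, the gene lists for PERK and the integrated stress response, HIF1 targets, glycolysis and CD8 T cell effector function pointed lower in LC3-GFP positive than negative cells, and those for ribosome biogenesis, proliferation and ER chaperones higher. Each of these 7 lists passed camera at its preset correlation and none passed with an estimated correlation (adjusted p = 0.235 to 0.375). The estimate was -0.041 for HIF1 targets and -0.026 for ribosome biogenesis, below the preset 0.01, and 0.049 to 0.299 for the others. Correlation among members thus cannot account for the loss in those 2 lists, where the estimated setting has few degrees of freedom. Ly6c2, which encodes a surface protein of memory and effector T cells (chromosome 15, 75108161 to 75111950), stood at 67.1 ± 1.35 CPM in positive and 212 ± 2.27 CPM in negative libraries (SD, n = 2 each) and was 3.15-fold lower. Prf1, which encodes the pore-forming protein perforin, stood at 184 ± 1.81 against 391 ± 7.48 CPM and was 2.13-fold lower. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3000 of 12022 genes were called, 1362 higher and 1638 lower in positive cells. Of these, 143 were higher and 471 lower by more than 1.5-fold, and 74 and 223 by more than 2-fold. The median size of a called log2 change was 0.318. Both libraries of a group lay above both of the other for 7398 genes (61.5%), where chance gives 33.3%. With library size alone in place of TMM, 2242 of 3445 called genes (65.1%) were higher, against 45.4% here. Without positive replicate 1 there were 1722 calls (683 higher, 1039 lower), without positive replicate 2 there were 1806 (738 and 1068), and DESeq2 called 1688 (705 and 983).

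Among the largest rises that the naming rule took, Cd74, the invariant chain of MHC class II (chromosome 18, 60803849 to 60812653), was 14.3-fold higher (15.4 ± 1.24 against 1.08 ± 0.344 CPM, adjusted p = 9.04e-10). Tox, a transcription factor linked to T cell exhaustion and development, was 2.40-fold higher (12.1 ± 0.858 against 5.02 ± 0.771 CPM). The gap junction gene Gja1, the interferon-inducible GTPase gene Iigp1, the membrane protein gene Myadm and Casp1, which encodes an inflammasome protease, rose, with log2 changes of 1.51, 1.44, 1.06 and 1.05. Igfbp7, Pkhd1l1 and Bahcc1 rose by 1.06, 1.02 and 0.96 on the log2 scale, and Tgoln2 by 1.31, though DESeq2 gave Tgoln2 an adjusted p of 0.499. Among the largest falls, Samd3 (-2.33), the decoy receptor gene Tnfrsf23 (-2.20), the phosphodiesterase gene Pde2a (-2.17) and the protease inhibitor gene Serpinb1a (-2.13) were each lower on the log2 scale. Itga7, which encodes an integrin chain, was 3.72-fold lower (14.6 ± 0.692 against 54.2 ± 1.54 CPM) and Tspoap1 was 3.66-fold lower. Ifi208, Arap3 and the histone gene Hist2h2aa1 also fell, with log2 changes of -1.95, -1.74 and -2.19, and DESeq2 gave Hist2h2aa1 an adjusted p of 0.167. Tgoln2, Hist2h2aa1, Ly6c2 and Ifi208 have close paralogs, so their counts are uncertain.

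**Figure D1:**
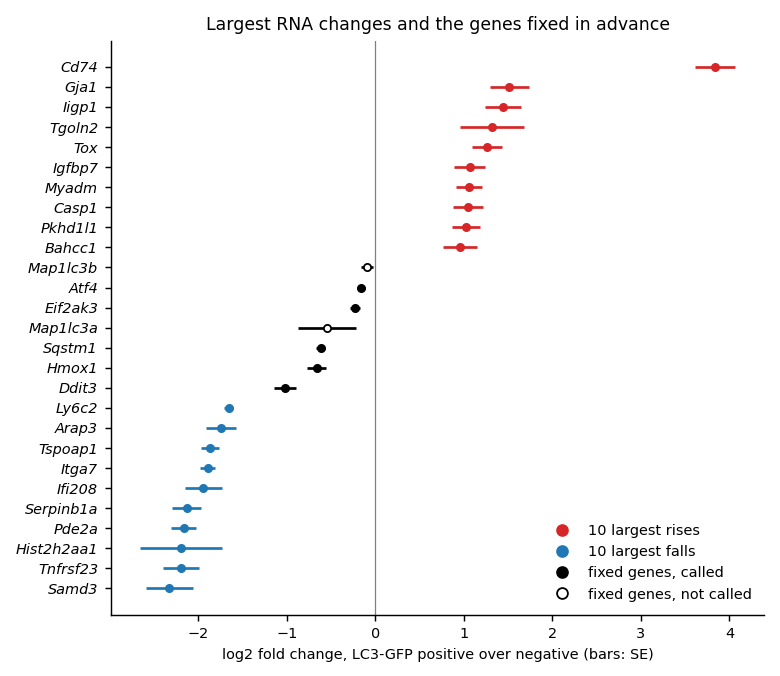
Log2 fold change of RNA (horizontal axis, LC3-GFP positive over negative, n = 2 each, bars showing the SE) for the 10 largest rises in red, the 10 largest falls in blue and 7 genes fixed in advance in black, with open circles for genes not called. Cd74 stands apart at 3.84, and Map1lc3a and Map1lc3b are the open circles.

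Transcripts of LC3 itself were not called between the groups. Map1lc3b, which encodes the main LC3 protein, stood at 56.2 ± 2.36 CPM in positive and 59.9 ± 2.23 CPM in negative cells (log2 -0.09, adjusted p = 0.367), and Map1lc3a at 1.94 ± 0.456 and 2.80 ± 0.893 CPM (log2 -0.55, adjusted p = 0.253). Of 32 tested members of the PERK and integrated stress response list, 20 fell, 1 rose and 11 were not called. Adjusted over the list alone, 21 fell and 1 rose. Ddit3, which encodes the stress transcription factor CHOP, fell from 21.7 ± 0.86 CPM in negative to 10.7 ± 1.15 CPM in positive cells (log2 -1.02), as did the pseudokinase gene Trib3 (-0.97) and the transcription factor gene Atf5 (-0.95). The member that rose was the stress-induced transcription factor gene Atf3 (0.34), whose adjusted p without positive replicate 2 was 0.107. The list passed camera at an adjusted p of 1.41e-08, with adjusted p = 0.375 with an estimated correlation. Eif2ak3, which encodes PERK, was lower by a smaller margin (110 ± 6.44 against 129 ± 3.30 CPM, log2 -0.23, adjusted p = 0.00599), and without positive replicate 2 its adjusted p was 0.164. Atf4, which encodes the main transcription factor of that response, had a log2 of -0.16 (adjusted p = 0.00988). Its adjusted p was 0.206 without positive replicate 1, 0.0963 without positive replicate 2 and 0.0782 with library size alone.

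ER chaperones, which fold proteins in the endoplasmic reticulum, went the other way, with 10 of 22 members higher and 0 lower (12 and 0 adjusted over the list alone). Hspa5, which encodes BiP, rose from 568 ± 19.9 to 718 ± 4.52 CPM (log2 0.34), and Sdf2l1, Hyou1 and Calr rose by 0.43, 0.29 and 0.29. This list passed at an adjusted p of 1.65e-05, with adjusted p = 0.293 with an estimated correlation. For mitophagy and selective autophagy receptors, 5 of 13 members fell and 0 rose, over all genes and adjusted over the list alone. They included the receptor gene Sqstm1 (118 ± 3.86 against 182 ± 6.16 CPM, log2 -0.62), the mitophagy kinase gene Pink1 (-0.55) and Bnip3 (-0.30). The adjusted p was 0.0192, it was 0.0511 with library size alone, and there was an adjusted p = 0.293 with an estimated correlation. The autophagy core machinery list did not pass (adjusted p = 0.425), with 4 of 28 members lower and 0 higher (2 and 0 adjusted over the list alone), among them Atg9a at -0.38. Lysosome and TFEB targets (3 higher and 6 lower of 23, and 4 and 7 adjusted over the list alone) did not pass either (adjusted p = 0.257), although the protease gene Ctsd fell (-0.54). In the NRF2 and heme or carbon monoxide response list, 2 of 26 members rose and 6 fell (2 and 7 adjusted over the list alone, adjusted p = 0.334). Hmox1, which encodes the heme oxygenase that makes carbon monoxide, fell from 29.9 ± 4.16 CPM in negative to 18.9 ± 1.24 CPM in positive cells, and its repressor gene Bach1 (-0.52) and the iron storage gene Fth1 (-0.28) also fell.

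**Figure D2:**
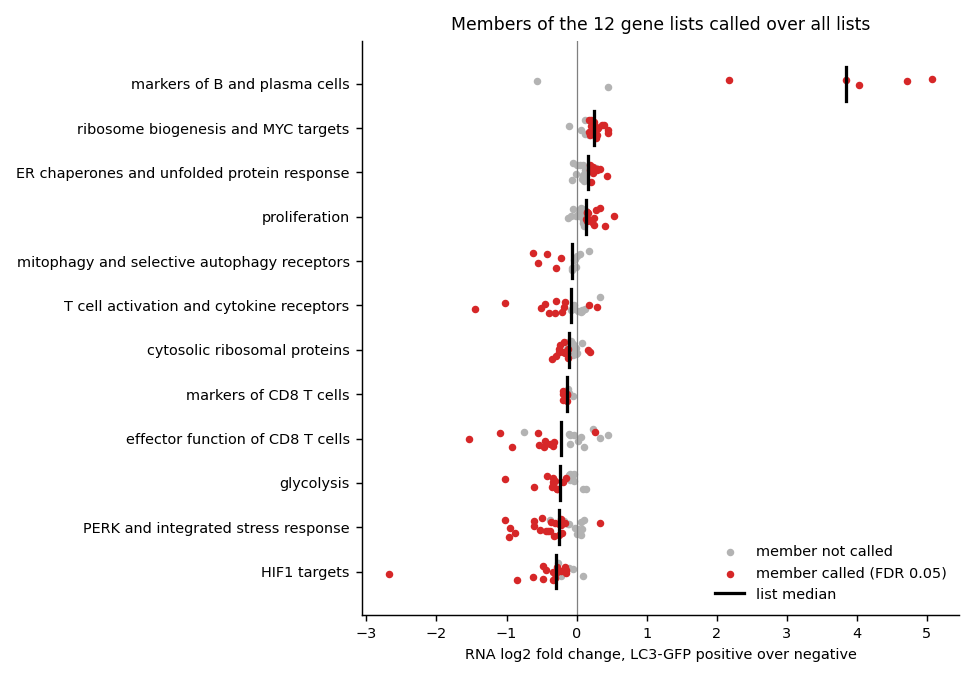
Log2 fold change of RNA (horizontal axis, LC3-GFP positive over negative) of each tested member of the 12 gene lists that passed camera, with called members in red, the others in grey and the list median as a black bar. Medians run from -0.291 for HIF1 targets to 3.84 for B and plasma cell markers, with library size alone the CD8 marker, ribosomal protein and mitophagy lists no longer passed, and none of the 12 passed with an estimated correlation (adjusted p = 0.235 to 0.501).

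Called genes of the hypoxia and glycolysis lists were lower in positive cells. For targets of the hypoxia factor HIF1, 15 of 20 members fell and 0 rose (16 and 0 adjusted over the list alone), including Ndrg1 (173 ± 7.66 against 312 ± 1.48 CPM, log2 -0.85), the ER oxidase gene Ero1l (-0.62) and P4ha2 (-0.48). For glycolysis, 12 of 20 members fell and 0 rose (13 and 1 adjusted over the list alone), including Aldoc (73.2 ± 3.76 against 148 ± 1.01 CPM, log2 -1.02), the glucose transporter gene Slc2a3 (-0.61), Aldoa (-0.42) and Pfkp (-0.35). HIF1 targets passed at an adjusted p of 6.23e-12 and glycolysis at 8.89e-10, with adjusted p = 0.235 with an estimated correlation for the first and adjusted p = 0.293 with an estimated correlation for the second. Slc2a1, Ldha and Pgk1 are on both lists. Mitochondrial lists did not pass. For oxidative phosphorylation, 6 of 32 members rose and 1 fell (the same numbers adjusted over the list alone, adjusted p = 0.113), led by the succinate dehydrogenase gene Sdhb at 0.26, and with library size alone the adjusted p was 0.0411. The tricarboxylic acid cycle had 1 of 18 members higher and 0 lower (1 and 0 adjusted over the list alone, adjusted p = 0.129). Mitochondrial biogenesis had 4 of 21 higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.233). Fatty acid oxidation had 2 of 20 higher and 1 lower (2 and 1 adjusted over the list alone, adjusted p = 0.308), with the nuclear receptor genes Pparg at 0.59 and Ppard at -0.42. In cholesterol and fatty acid synthesis, 4 of 26 members rose and 8 fell (4 and 9 adjusted over the list alone, adjusted p = 0.308), with Fasn at 0.28 and Scd1 at -0.38.

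Most called effector and activation genes of T cells were lower in positive cells, and memory and exhaustion genes moved both ways. For effector function of CD8 T cells, 10 of 22 members fell and 1 rose (11 and 1 adjusted over the list alone), including Prf1, the chemokine gene Ccl5 (20.5 ± 0.478 against 38.9 ± 2.13 CPM, log2 -0.92) and Id2 (-0.56). The member that rose was the lymphotoxin gene Lta (0.26), with an adjusted p of 0.0847 without positive replicate 2. For T cell activation and cytokine receptors, 10 of 21 fell and 2 rose (10 and 3 adjusted over the list alone), including the interleukin 18 receptor gene Il18r1 (32.1 ± 0.0386 against 87.6 ± 0.964 CPM, log2 -1.45), Fosl2 (-1.03) and Tnfrsf9 (-0.45), a costimulatory receptor gene. The interleukin 2 receptor gene Il2ra (0.29) and Myc (0.18) rose, and Myc had an adjusted p of 0.119 without positive replicate 1 and 0.0777 without positive replicate 2. The adjusted p was 5.21e-06 for the effector list and 0.000116 for the activation list, each with adjusted p = 0.293 with an estimated correlation. In memory and stemness, 6 of 23 members rose and 5 fell (6 and 7 adjusted over the list alone). Eomes (-1.45) and Ly6c2 fell, while Cxcr3 (0.70) and Id3 (0.64) rose. This list had an adjusted p of 0.0929, and of 0.0234, lower in positive cells, without negative replicate 1. Among inhibitory receptors and exhaustion genes, 5 of 20 rose and 4 fell, with the same numbers adjusted over the list alone. Tox, Btla (0.56) and Irf4 (0.25) were among those that rose. The inhibitory receptor genes Havcr2 (32.7 ± 0.247 in positive against 68.5 ± 7.71 CPM, -1.07) and Lag3 (-0.54) and the ectonucleotidase gene Entpd1 (-1.15) were among those that fell. The median and mean of this list were above 0 and camera pointed down (adjusted p = 0.576), and up without negative replicate 2 (0.984).

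Ribosome biogenesis genes were mostly higher in positive cells, while ribosomal protein genes that were called were mostly lower. For ribosome biogenesis and MYC targets, 19 of 25 members rose and 0 fell (22 and 1 adjusted over the list alone), including Utp20 (152 ± 0.918 against 112 ± 7.12 CPM, log2 0.45), the pseudouridine synthase gene Dkc1 (0.44) and the nucleolar gene Gnl3 (0.39). For proliferation, 14 of 32 rose and 0 fell (15 and 0 adjusted over the list alone), including the cyclin gene Ccne2 (54.5 ± 2.12 against 37.9 ± 0.354 CPM, log2 0.53), Tyms (0.41) and Pcna (0.34). The first list passed at an adjusted p of 2.7e-10 and the second at 1.65e-05, with adjusted p = 0.235 with an estimated correlation for ribosome biogenesis and adjusted p = 0.293 with an estimated correlation for proliferation. Cytosolic ribosomal proteins had 11 of 26 members lower and 2 higher (14 and 2 adjusted over the list alone), among them Rps6 (-0.35) and Rpl10a (-0.25). Their adjusted p was 0.0112, with adjusted p = 0.501 with an estimated correlation, and it was 0.0917 with library size alone, 0.0605 without positive replicate 1 and 0.0889 without negative replicate 2. Apoptosis and p53 targets had 8 of 23 higher and 3 lower (11 and 5 adjusted over the list alone), with Ccng1 at 0.35 and the pro-apoptotic gene Bcl2l11 at -0.95, and an adjusted p of 0.127, or 0.0167 without negative replicate 2. Among chromatin and histone methylation enzymes, 5 of 25 rose and 8 fell (5 and 8 adjusted over the list alone), with the histone demethylase genes Kdm6b (-0.92) and Kdm5b (-0.58), Jarid2 (-0.75) and Tet2 (-0.41) lower and the methyltransferase gene Ezh2 (0.33) higher. The median of this list was above 0, its mean below 0 and camera pointed down (adjusted p = 0.124). In the interferon response, 4 of 22 rose and 5 fell (5 and 6 adjusted over the list alone), with Gbp2 (0.57) higher and Usp18 (-1.52) lower, and the median and mean were below 0 while camera pointed up (adjusted p = 0.712).

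The ribosomal RNA precursor Rn45s took 1.43% and 1.51% of counts in the positive and 3.20% and 3.58% in the negative libraries (log2 -1.27). Its share thus differed between the same libraries as every list above, whatever the direction of the list. Without Rn45s, a setting chosen after seeing the data, 2998 genes were called, 2994 of them shared with the 3000.

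Markers of other cells moved both ways between the populations, with B cell markers at low levels. For B and plasma cells, 5 of 7 tested markers rose and 0 fell, with the same numbers adjusted over the list alone. Those that rose included Cd79a, Ms4a1, Cd22 and Jchain, the last with an adjusted p of 0.0713 without positive replicate 1. Cd79a, a chain of the B cell receptor, stood at 2.04 ± 0.037 CPM in positive and 0.135 ± 0.00736 CPM in negative cells, a ratio of 15.2 on 69 and 4 summed counts (exact 95% interval 5.66 to 57.2). Ms4a1, which encodes CD20, had 37 counts against 1, a ratio of 32.5 (5.48 to 1320). The list median was 3.84 by fitted values and 2.45 with the 3 genes of 3 or fewer negative counts at the lower bound of their interval. This list passed at an adjusted p of 0.000152, with adjusted p = 0.293 with an estimated correlation. Among macrophage, monocyte and dendritic cell markers, 3 of 7 rose (Cd74, H2-Aa and Mpeg1) and 2 fell (Cd68, -1.54, and H2-Ab1, 49.5 ± 3.84 against 69.1 ± 3.02 CPM), with the same numbers adjusted over the list alone. The median was -0.354 with a mean of 1.352 (adjusted p = 0.0749, and 0.0262 without positive replicate 1). Cd4 was 4.62-fold higher (3.90 ± 0.715 against 0.835 ± 0.192 CPM), while the helper lineage factor genes Zbtb7b (-0.48) and Gata3 (-0.38) were lower. Kit (-1.29), the NK receptor gene Klrb1c (-1.59) and Eomes were lower, and 0 of 5 melanoma and stroma markers were called by edgeR. CD8 T cell markers had 7 of 10 members lower and 0 higher (8 and 0 adjusted over the list alone), with Cd8a at 529 ± 7.61 against 600 ± 25.2 CPM (log2 -0.18). The CD8 list had an adjusted p of 0.0112, with adjusted p = 0.293 with an estimated correlation, and 0.0511 with library size alone. For Cd8a alone the adjusted p was 0.00616, 0.144 without positive replicate 1, 0.0685 without positive replicate 2 and 0.051 with library size alone.

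Open chromatin in vitro differed between the sorted populations more than between other pairings of the same libraries. Peaks merged into 73648 regions, of which 39655 (53.8%) were found in all 4 libraries, 5911 in both positive libraries and neither negative one, and 2448 in both negative libraries and neither positive one. Positive-only regions lay in the B cell genes Cd79a (promoter, chromosome 7, 24896293 to 24898109) and Blk (gene body, chromosome 14, 63388767 to 63389631), in Bach2, a repressor that restrains effector differentiation (gene body, chromosome 4, 32563996 to 32565266), and in the autophagy gene Atg5 (gene body, chromosome 10, 44321640 to 44322385). Negative-only regions lay in Pdcd1, which encodes the inhibitory receptor PD-1 (gene body, chromosome 1, 94047817 to 94048589), in the interleukin 12 receptor gene Il12rb2 (gene body, chromosome 6, 67301890 to 67302673), and in the autophagy genes Atg14 and Vmp1. By the caller's score within each library, in percent with higher being stronger, the positive-only regions just named had mean ranks of 50.6 (Atg5) to 67.7 (Blk). The negative-only ones ranked lower, from 33.2 (Atg14) to 42.6 (Il12rb2), with Pdcd1 at 39.6. A peak not called in the other group may lie just under the caller's cutoff, so closed chromatin there is not shown. Over all genes, the highest-ranked positive-only regions included Tenm4, Cds1, Sec14l1 and Itpr1, and negative-only ones Dhx32, Tnrc6a and Clic5. Bach2, Vmp1, Itpr1, Dhx32 and Tnrc6a held regions of both kinds. Group-only regions totalled 8359, against at most 2166 in the other splits. With the same number of top peaks in each library there were 4466 positive-only and 3838 negative-only regions. With 2 libraries a side no permutation test over these libraries can pass, since the smallest exact p is 0.333. Leaving out 1 library raised the total to 13184 (negative replicate 1), 13598 (negative replicate 2), 13097 (positive replicate 1) or 16448 (positive replicate 2), since fewer libraries then had to share or lack a region.

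No gene list was enriched among in vitro group-only regions by Fisher's exact test. Memory and stemness genes were among the closest, with 9 of 23 holding a positive-only region (among them Bach2, Bcl2, Cd28, Cd44, Il7r, Lef1, Satb1 and Tcf7) and 6 of 23 a negative-only one (among them Bach2, Bcl2, Cd44, Lef1 and Satb1), each at an adjusted p of 0.246. Random lists matched on number of regions held 7.07 and 4.15 on average (permutation p = 0.215 and 0.199). Among chromatin enzymes, 6 of 25 (Dnmt3a, Ezh1, Jarid2, Kdm1a, Kdm5b and Tet2) held a negative-only region (adjusted p = 0.246), and Dnmt3a and Kdm1a a positive-only one too. B and plasma cell markers had 5 of 12 (Blk, Cd79a, Ebf1, Ms4a1 and Pax5) with a positive-only region, at an adjusted p of 0.444, and macrophage, monocyte and dendritic cell markers 5 of 13 (Adgre1, Clec9a, Fcgr1, Flt3 and Mpeg1), at an adjusted p of 0.521. Over 62 tests of lists and directions, 0 passed the adjustment and 5 had an unadjusted p under 0.05, and with random lists matched on number of regions 0 passed and 4 were under 0.05. The number of peaks was 58815 ± 6995 in positive and 53055 ± 4838 in negative libraries (SD, n = 2 each, two-sided exact permutation p = 0.667). The mean Jaccard index was 0.699 within and 0.622 between groups (one-sided exact permutation p = 0.333, the smallest possible).

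**Figure D3:**
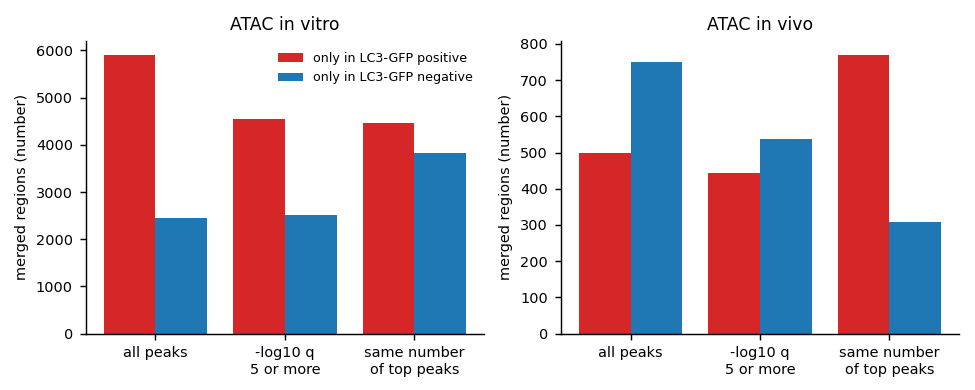
Number of merged ATAC regions (vertical axis, from 0) found in all libraries of the LC3-GFP positive group and none of the negative group (red), or the reverse (blue), in vitro on the left and in vivo on the right, for all peaks, for peaks with -log10 q of at least 5 and for the same number of top peaks per library. Positive-only regions outnumber negative-only ones in vitro at each setting, while in vivo the order turns from 500 against 750 with all peaks to 770 against 308 with top peaks.

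Genes with in vitro negative-only regions had slightly lower RNA changes than genes with positive-only regions. The median RNA log2 fold change was 0.0079 over 1529 genes with positive-only regions and -0.0362 over 618 genes with negative-only regions, a difference of 0.0441 (two-sided permutation p = 0.00047). The median was 0.0096 over 8820 genes with neither. Among called genes, 186 of 404 with positive-only regions were higher in RNA, against 61 of 187 with negative-only regions (Fisher's exact p = 0.00228) and 1362 of 3000 over all called genes. Tox, Btla and Cd79a, higher in RNA, each had 1 positive-only region, and Tspoap1, Ifi208, Jarid2, Kdm5b and Tet2, lower in RNA, had negative-only regions. Others ran opposite, with a positive-only region in Havcr2 and Slc2a3, lower in RNA, and a negative-only region in Igfbp7, higher in RNA. With the same number of top peaks the difference was 0.0231 and no longer passed (permutation p = 0.0661). Genes are not independent replicates, and RNA and ATAC came from separate libraries.

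T cells recovered from tumours also differed by population, under a stricter definition, since 4 libraries had to hold a region and 4 to lack it. Of 72327 merged regions, 20969 (29%) were found in all 8 libraries, 500 in all 4 positive and no negative library, and 750 in all 4 negative and no positive library. Positive-only regions lay in Tox (gene body, chromosome 4, 6969766 to 6971099), in Lef1, a transcription factor of naive and memory T cells (gene body, chromosome 3, 131190493 to 131191664), in the DNA demethylase gene Tet1, the autophagy gene Uvrag and the lactate transporter gene Slc16a1. Negative-only regions lay in the autophagy gene Atg10 (gene body, chromosome 13, 90980814 to 90982004 and 91205961 to 91207074), in Bach2 (chromosome 4, 32374857 to 32376872), in the adhesion receptor gene Cd44, in Pfkfb3, which controls glycolysis, and in the exhaustion-linked gene Tox2. Mean ranks by the caller's score ran from 33.2 (Slc16a1) to 59.6 (Tox) percent for these positive-only regions. For the negative-only ones they ran from 21.1 (Tox2) to 48.3 (Atg10), with Cd44 at 26.8 and Bach2 at 33.8. The highest-ranked regions over all genes included Kif1b, Lbp and Mia2 (positive-only) and Fnbp1, Bcr and Itpr2 (negative-only), and Itpr2 held both kinds. The total of 1250 group-only regions exceeded that of each of the other 34 splits, the highest being 270. With the same number of top peaks the balance turned to 770 positive-only and 308 negative-only regions. Negative replicate 2 shared few regions with the other libraries, as 40.7% of its regions were found in it alone, and without it there were 611 positive-only and 1319 negative-only regions. Without positive replicate 1, which had the shortest peak list, there were 1208 and 763.

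In vivo, no gene list was enriched in the planned test, with 0 of 62 tests under an unadjusted p of 0.05 by Fisher's exact test. With the same number of top peaks, 5 of 22 memory and stemness genes (among them Bach2, Cd44, Lef1 and Satb1) held a positive-only region at an adjusted p of 0.0218, the 1 list that passed there. Random lists matched on number of regions are not given for that setting. With all peaks Lef1 held a positive-only region and Bach2 and Cd44 a negative-only one. The smallest adjusted p without negative replicate 2, chosen after seeing the data, was 0.894. Libraries held 34644 ± 4841 peaks in positive and 41517 ± 9672 in negative mice (SD, n = 4 each, two-sided exact permutation p = 0.314). The mean Jaccard index was 0.613 within and 0.570 between groups, a difference of 0.0421 (one-sided exact permutation p = 0.0286, 2 of 70 groupings). The exact permutation p rose to 0.0571 without negative replicate 4, 0.286 without positive replicate 1, 0.314 without positive replicate 2, 0.371 without positive replicate 3 and 0.371 without positive replicate 4, and it was 0.0286 without negative replicate 2.

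**Figure D4:**
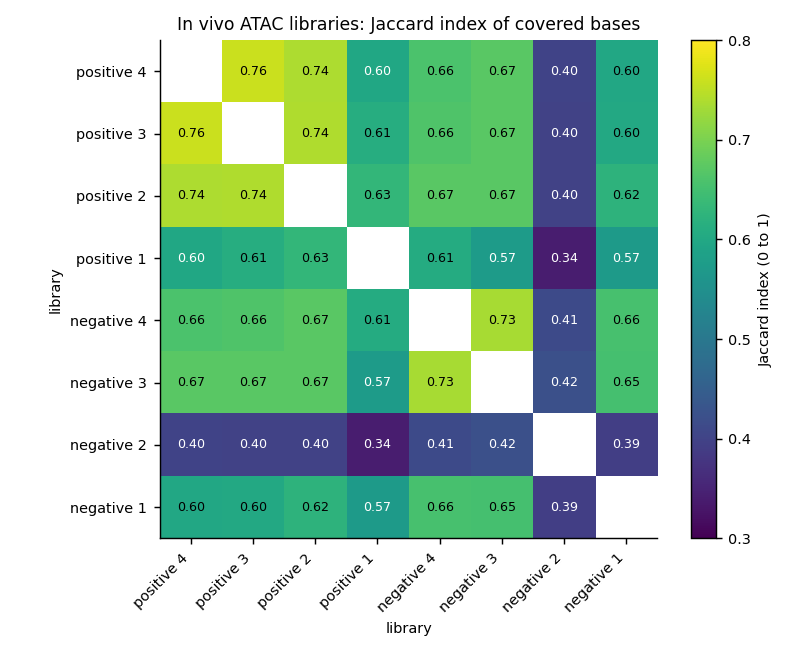
Jaccard index of bases covered by peaks for each pair of the 8 in vivo ATAC libraries (both axes list libraries, the colour scale runs from 0.3 to 0.8). Negative replicate 2 has a mean of 0.395 with the other libraries, whose means are 0.563 to 0.640.

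Regions that separated the groups in both experiments mostly did so in opposite directions. They were few, as 0.08% to 1.67% of in vitro regions of a kind were group-only in vivo in a given direction with all peaks. Fisher's exact tests of direction take these regions as independent, though they come from 2 and 2 libraries in vitro and 4 and 4 in vivo. Direction was not set beside other splits of the libraries. Of 71 such regions, 5 were positive-only and 7 negative-only in both, 18 were positive-only in vitro and negative-only in vivo, and 41 were negative-only in vitro and positive-only in vivo. The same direction was thus shared by 12 of 71 (16.9%, Fisher's exact p = 2.6e-07), where the totals of each kind alone give 31.8. With the same number of top peaks it was shared by 11 of 116 regions (p = 0.000113, Fisher's exact test), where the totals alone give 20.7. There 99 were negative-only in vitro and positive-only in vivo and 5 negative-only in both, while those positive-only in vitro split evenly, 6 each way. It was shared by 139 of 368 regions with in vivo ones in at least 3 libraries of a group and at most 1 of the other, against 181 (p = 1.27e-05, Fisher's exact test). Without in vivo negative replicate 2, a setting chosen after seeing the data, it was 44 of 116 (37.9%, Fisher's exact p = 0.000552), against 61.3. Regions negative-only in vitro then split nearly evenly, 42 positive-only and 37 negative-only in vivo. Of those positive-only in vitro, 30 were negative-only and 7 positive-only in vivo.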

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

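Among the tests here, that of B cell genes at in vitro ATAC regions was written down before its result was seen, and every other test here was chosen only after the result it bears on had been seen. Of 16 tests for a library far from the other 3 of its in vivo group, 5 found one, where chance finds about 1 in 20, and several of the measures are related. In vivo positive replicate 1 had 27406 peaks against 36539 to 37477 in the other positive libraries. Its mean Jaccard index was 0.614 to its own group (0.699 to 0.704 for the others), 0.563 to all other libraries (0.633 to 0.640), and 0.609 to them with the same number of top peaks (0.660 to 0.667), values in parentheses being the other positive libraries. No explanation was tested for that library. In in vivo negative replicate 2, 40.7% of regions were found in that library alone, against at most 6% in the other negative libraries.

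In vivo negative replicate 2 also had a mean Jaccard index of 0.395 to the others. A longer peak list is argued against, since with the same number of top peaks its mean index was 0.416, below the 0.609 to 0.667 of the others. DNA of other cells may be a source of its regions, since 13 of 25 marker genes of the macrophage, neutrophil and melanoma lists with a region among top peaks had one of that library alone (52%, against 21.6% of other genes, one-sided Fisher's exact p = 0.000805), where random lists matched on gene length held 4.97 (permutation p = 0.0002). Of these genes 7 were of the macrophage list, 3 of the neutrophil list and 3 (Cdh5, Mitf and Pecam1) of the melanoma and stroma list. Dct, Tyrp1, Tyr, Pmel, Mlana and Sox10 had none, though Dct had one with all peaks, so the count does not point at melanoma cells in particular. With top peaks 3 of 13 CD8 T cell markers had a region in negative replicate 2 (10 to 13 elsewhere), but with all peaks 13 of 13 did, and the sort on Vβ13 and CD8 should remove other cells. A wrong label is argued against as the source of its distance. Its mean index was 0.385 ± 0.029 to the positive and 0.409 ± 0.016 to the other negative libraries (SD). Positive libraries had means of 0.614 to 0.704 to their own group. Whether its label is right cannot be told apart, since the first mean minus the second was -0.025, within the SD of 0.029. Each positive library lay nearer its own group by 0.029 to 0.058, within the SD for replicates 2, 3 and 4. Negative replicate 2 held 3 peaks on chromosome Y, against 7 to 17 in the other libraries, which the test for a far library did not flag. A difference by mouse or tumour stays open, as untested.

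B cell transcripts were higher in LC3-GFP positive RNA, with Cd74 at 15.4 and 1.08 CPM, Cd79a at 2.04 and 0.135 CPM and H2-Aa at 3.07 and 0.199 CPM in positive and negative cells, while H2-Ab1 was lower (49.5 and 69.1 CPM). A lower share of CD8 T cells with every other cell type higher alike is argued against, since of 18 tested markers of other types (B and CD4 T cells aside) 5 were lower and 3 higher (Cd74, H2-Aa and Mpeg1, which B cells also express), though this rests on Cd68 and Klrb1c, since Eomes, Kit and H2-Ab1 have baselines that would hide a small share, and 7 of 10 CD8 T cell markers were lower too. A small number of B cells in the positive RNA libraries cannot be told apart from expression by the T cells, since 5 of 7 markers of the list fixed in advance rose but 1 of 11 of a second list (Bank1) did and 2 fell, and 7 of those 11 stood at 1 CPM or more in negative cells, where a small share would not show, while all 4 under 1 CPM, a restriction chosen after the result, were above 0. B cells in the in vitro positive ATAC libraries may be a source of some positive-only regions, since 14 of 34 genes of both lists held one (41.2%, against 16.6% of other genes, one-sided Fisher's exact p = 0.000593; mean of 7.86 in matched random lists, p = 0.0032), and 2 of 34 a negative-only one (Fisher's exact p = 0.765), while 5 of 13 macrophage, monocyte and dendritic cell markers held one too (matched random lists p = 0.0022, adjusted p = 0.136), and with top peaks the numbers were 15 of 33 for the B cell lists (Fisher's exact p = 7.45e-06) and 1 of 12 for the macrophage list. The labels describe purified CD8+ T cells, which should hold no B cells, and a difference of the T cells themselves by LC3-GFP state stays open, as untested.

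The ribosomal precursor Rn45s and histone transcripts were higher in LC3-GFP negative RNA, with 24 of 48 replication-dependent histone genes lower and 0 higher in positive cells (median log2 -1.11), many of them near-identical copies with uncertain counts. Rn45s taking counts from other genes is argued against, since the difference in its share (1.47% and 3.39%) can shift the others by 0.028 on the log2 scale, and this test replaced the histone median without Rn45s, which TMM could hardly move. Fewer cells in S phase among positive cells is argued against by the proliferation list, of which 14 members rose and 0 fell, though as a list it had an adjusted p of 0.293 with an estimated correlation. More RNA without a poly(A) tail in the negative libraries may be a source, since those 24 histone genes, Rmrp (3 counts in positive and 85 in negative cells, ratio 32.3, exact 95% interval 10.7 to 160) and Rpph1 (-1.11) were lower in positive cells, while of 9 histone genes with a tail 1 was lower and 2 higher. Of long nuclear RNAs 3 of 5 were lower (Malat1, Neat1 and Kcnq1ot1) and Mir155hg higher, the tailed host genes Mir22hg and Mir17hg were lower and higher, and a difference of the cells by LC3-GFP state stays open, as untested.

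For the in vivo regions, 1 of the 35 splits of the 8 libraries, the real one, gave as many regions found in all libraries of a group and none of the other (1250, highest other 270). The same held for regions in at least 3 of 4 libraries of a group and at most 1 of the other (5795, highest other 4900). By this count chance is argued against for both, at a share under 0.05. It is not excluded, since 1 of 35 is the smallest share possible and the margin is narrow for the second.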

How the results depend on the processing

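The tests without Rn45s, with matched random lists, and of ATAC lists and direction without in vivo negative replicate 2 were chosen only after results were seen. No result past its threshold turned its direction. Camera's direction turned for lists that did not pass, up for exhaustion with the replicate block (adjusted p = 0.911) and without negative replicate 2 (0.984), and up for melanoma and stroma markers without positive replicate 1 (0.638) and without negative replicate 1 (0.856). The gene Itga2b, not called, also changed sign in 1 setting. In RNA, DESeq2's size factors, limma-voom, the filters on low counts and leaving out Rn45s gave 2985 to 3017 calls. Of 129 named genes, 71 kept their side of the threshold under every alternative and 107 under all but leaving out a library and glmTreat. DESeq2 called 1688 genes (705 higher, 983 lower), glmTreat 606 (134 and 472) and library size alone 2242 higher. For glmTreat a change of more than 1.2-fold is asked. Library size alone leaves out the TMM factors, which moved the median log2 change of all genes from 0.002 to 0.065. The cause was not tested for DESeq2. By camera with an estimated correlation, a setting with few degrees of freedom, 0 of 12 lists passed. With fry, which tests a list against no change and not against other genes, the PERK list (0.06), proliferation (0.06) and ribosomal proteins (0.119) no longer passed and the tricarboxylic acid cycle did (0.0369). With the same number of top peaks there were 3838 in vitro negative-only regions, 770 positive-only and 308 negative-only in vivo, 1 ATAC list in vivo, and a difference of 0.0231 in the RNA of genes with group-only regions. Positive-only regions in vivo then outnumbered negative-only ones, against 500 and 750 with all peaks, and the cause was not tested. Leaving out 1 library gave 1722 to 3451 RNA calls (683 to 1615 higher, 1039 to 1836 lower). It gave 13097 to 16448 group-only regions in vitro (7068 to 13304 positive-only, 3144 to 6530 negative-only) and 1386 to 1971 in vivo (541 to 1208 and 763 to 1319), where fewer libraries have to share a region. The in vivo similarity difference ran from 0.0159 to 0.0727. Where a group was left with 1 RNA library, it was assumed to vary like the other group. Deviations of same-numbered RNA libraries had a correlation of 0.065 over 2 pairs, too few to show or exclude pairing. With the replicate number as a block there were 3568 calls, the p53 list passed (0.044) and no other list call changed, and the sign-flip permutation of peak numbers gave p = 0.5 in both experiments. In vitro that is the smallest p that 2 pairs allow, so the test could not pass there. Planned fits on ATAC counts were not run because the lists hold peaks, not counts per region. Peak number limits the ATAC comparisons, as read depth is unknown.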

Other observations

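The gene families here share a stem of their symbols, and their tests were chosen only after the data were seen. Of 128 families tested by camera on the RNA, 10 had an adjusted p of 0.05 or less, and with an estimated correlation 0 did (smallest adjusted p 0.759). The few degrees of freedom of that setting limit it here too. In LC3-GFP positive cells, nuclear pore genes (Nup) had 8 of 20 members higher and 0 lower (adjusted p = 0.00186), splicing factor genes (Srsf) 6 of 11 and 0 (0.0086) and replicative helicase genes (Mcm) 6 of 10 and 0 (0.014). RNA helicase genes (Ddx) had 10 of 35 higher and 1 lower (0.029), and mitochondrial ribosomal protein genes (Mrpl) 8 of 49 and 0 (0.0243). Ribosomal protein genes had 22 of 51 lower and 2 higher (Rpl, 0.0086) and 16 of 47 lower and 2 higher (Rps, 0.0214). Histone demethylase genes (Kdm) had 8 of 18 lower and 1 higher (0.0086), Pik genes, mostly of phosphoinositide kinases, 7 of 14 and 0 (0.0213) and histone genes (Hist) 24 of 48 and 0 (0.000129). With library size alone, which moved the median of all genes to 0.065, none of these 10 medians changed sign, and the Rps family no longer passed (0.0536).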
